A study of Mus musculus with 16 samples.

How the data were processed

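RNA from 16 livers of male ICR mice was sequenced, with 4 livers each for plain water and for polystyrene of 3 diameters (80 nm, then 0.5 µm, then 5 µm). Groups and replicate numbers were taken from the sample labels. The authors deposited a table of 20925 genes whose columns hold, per the file headers, estimated counts, TPM and FPKM for each library. The deposited estimated counts are not normalized, between 92.1% and 92.8% of them are whole numbers, and they were rounded to whole numbers here. TPM, scaled by the authors to transcript length and to a fixed sum per library, was used only for a check. FPKM, scaled by the authors to transcript length and mapped reads, was not used here. A further deposited table gives TPM for 77949 transcripts. Transcript TPM values summed per gene matched the gene TPM within 0.5 TPM in 99.981% of 334352 values, over 20897 genes. The aligner, the counting program, the annotation version and strandedness are not given in the sources used here. The build GRCm38.p6 and the R package limma are named per the submitters' processing notes, without a role for limma. No mitochondrially encoded gene is listed in the gene table, so that list was not tested.

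Gene identifiers are NCBI gene ids, and 20864 matched the RefSeq gene table of the same build, from which coordinates were taken, 1-based. Library totals ran from 15818685 to 17031720 estimated counts, and the median SE of a log2 fold change was 0.15 for 80 nm against water. Precision also depends on level, since genes with few counts have wider errors. All 24 pairs of libraries within groups differed by more than sampling noise, with chi-square per degree of freedom between 27.7 and 151, so none was treated as a duplicate.

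Tests were run in R 4.3.3. Genes were kept with filterByExpr on the group (minimum count 10), which left 12298. The main test was edgeR 4.0.16 with TMM normalization, robust quasi-likelihood fitting and all 4 groups in a single fit on group only. The seed of all random draws was 1. The test was two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM, counts scaled to the same total, on the TMM-scaled library sizes, given as mean ± SD over 4 livers, and log2 levels used a prior count of 2. The 7 contrasts were each size against water, each pair of sizes and the mean of the 3 sizes against water. Exact permutation tests, two-sided, ran over all 70 relabellings of 4 against 4 livers on single measures, and were not adjusted over measures.

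Fixed lists of genes (37 in all, 34 with enough measured members) covered liver metabolism, receptor targets, stress responses, matrix, markers of other cell types, clock and sex-biased genes. They were tested with camera in limma 3.58.1 on log2 levels with an inter-gene correlation preset to 0.01, adjusted by Benjamini-Hochberg over 238 tests, and again with the correlation estimated from the data. With an estimated correlation no list was called in any of the 7 contrasts, the smallest adjusted p being 0.81. The listed name Slp was matched to C4a.

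The contrasts, lists, tests, alternatives and the rule for named genes were written before the data were examined. The rule took up to 10 genes per direction with the largest called change whose groups do not overlap and whose mean is at least 1 CPM (with fewer than 5, the 5 with the smallest p), 3 per direction between sizes, up to 4 members of each list described and a fixed panel of genes. Predicted genes were counted and not named. Which of the genes taken by the rule are named in the text was decided after their values were seen, and results of some genes are not reported here. The clock score was defined after seeing the data.

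The edgeR fit was tested on simulated counts drawn from the real means, spread and library sizes for 12298 genes, 200 of them changed. At 80 nm against water it recovered 38.8% of genes changed 1.5-fold, 64.2% at 2-fold and 92.4% at 4-fold. At 0.5 µm it recovered 31.3%, 80.6% and 89.4%, and at 5 µm 37.3%, 80.6% and 87.9%. Unchanged genes made up 4.41%, 5.63% and 4.86% of the calls.

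Alternatives set beforehand were DESeq2 size factors, no filter, a filter of 5 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, a fit of only the groups compared, 2 other thresholds and leaving out each library. Chosen after seeing the data were the clock score as a covariate and leaving out the Mup genes. Shared controls were handled with 20 simulations of unchanged groups and with all splits of the 4 water livers into pairs.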

Results

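Messenger RNA was measured by sequencing in livers of male ICR mice, an outbred strain. The mice were 6 weeks old at the start and drank plain water or water with polystyrene particles at 1 mg/L for 12 weeks. The particles had diameters of 80 nm, 0.5 µm or 5 µm, and each of the 4 groups had 4 livers. The title of the series asks about fibrosis and lipid deposition in the liver and speaks of hub genes that it does not name. Each of the 16 libraries held between 15818685 and 17031720 estimated counts over 20925 listed genes, of which 17616 had a count and 12298 entered the tests. The smallest exact permutation p that 4 livers against 4 can give is 0.0286. P-values here measure the spread between these libraries, taken as separate mice from the labels.

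Genes of the circadian clock, which runs daily rhythms in the liver, differed between water and the 2 larger sizes, and fewer of them between water and 80 nm. A clock score was set, after their values were seen, as the mean log2 level of Dbp, Tef and Per3 minus that of Arntl, Npas2 and Clock. It was -0.66 ± 1.65 in water, 1.73 ± 0.62 at 80 nm, 5.87 ± 0.19 at 0.5 µm and 5.87 ± 0.39 at 5 µm (mean ± SD, n = 4 each). Water replicate 3 had the highest score of its group, 1.67, within the range of the 80 nm livers (1.16 to 2.39), and the other water livers lay between -2.06 and -0.70. Major urinary proteins, the pheromone carriers made by male liver, took 24.2% ± 6.13 of all counts in water. In the polystyrene groups that share was 11.6% ± 2.23, 12.8% ± 1.64 and 11.8% ± 3.71 from the smallest to the largest particle (mean ± SD, n = 4; exact permutation p = 0.0286 against water for each). The sum covers 24 Mup genes, near-identical copies whose single values are uncertain. Water replicate 3 held the highest share, 32.7%.

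**Figure D1:**
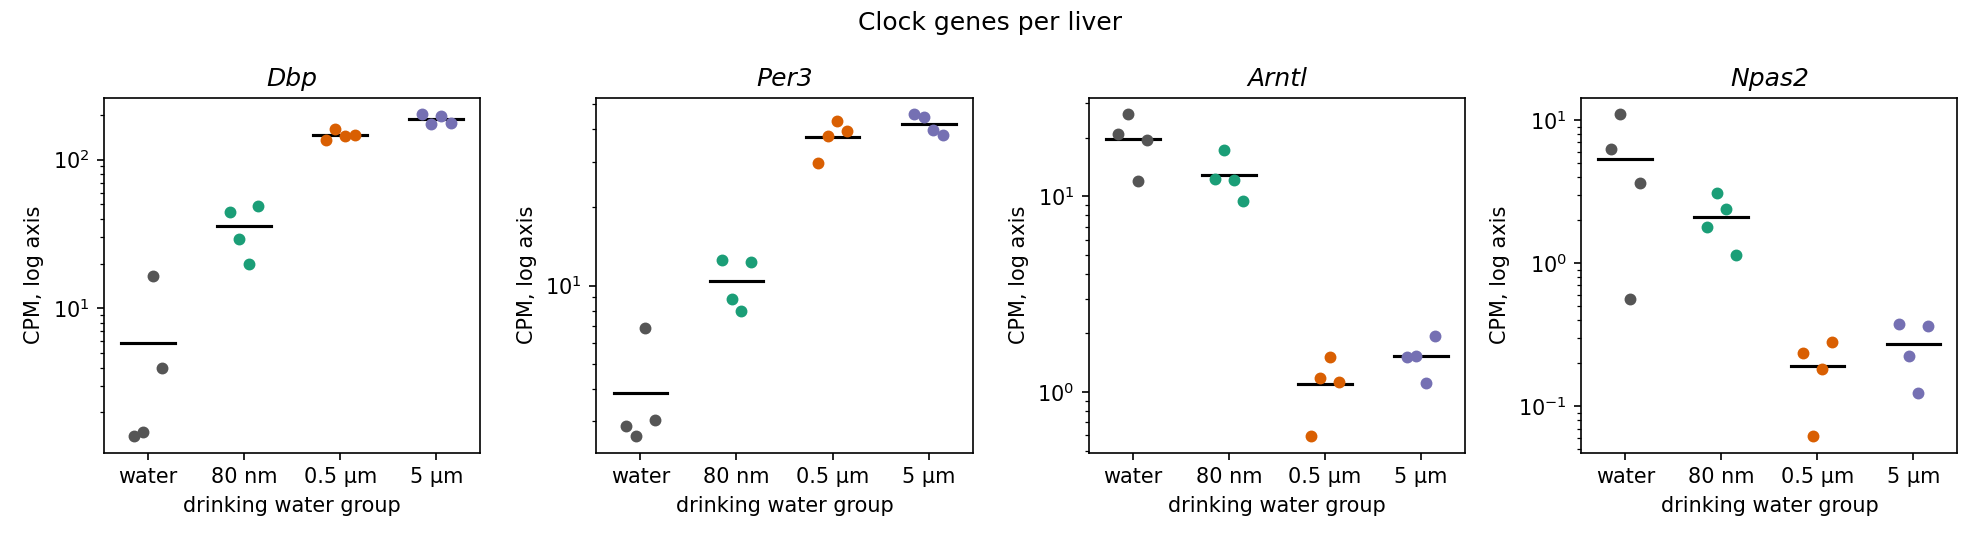
Levels of Dbp, Per3, Arntl and Npas2 in CPM on log axes, with a point for each of the 16 livers and a line at each group mean. Dbp and Per3 lie lowest in water and Arntl and Npas2 lie lowest at 0.5 µm and 5 µm.

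**Figure D2:**
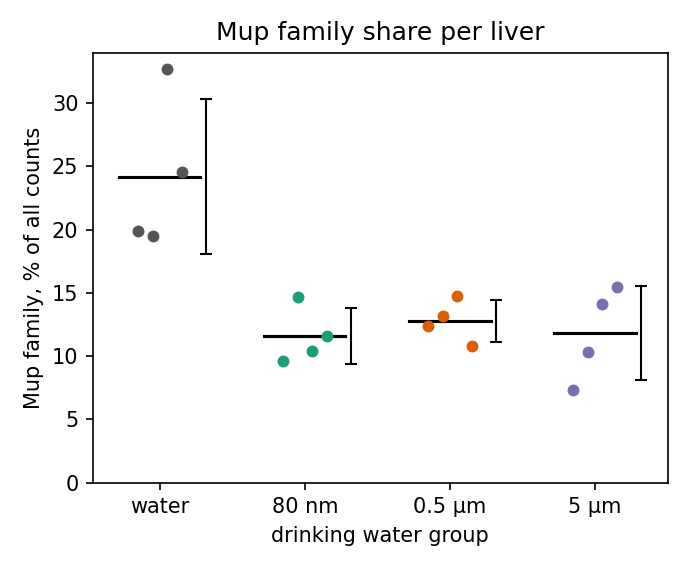
Share of all counts in 24 Mup genes, in percent, with a point per liver, a line at the group mean and a bar of 1 SD each way. The 4 water livers lie between 19.5% and 32.7% and the 12 others between 7.29% and 15.5%.

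Acot3, Abcc3 and Nr1i3 were taken before the data were examined as the hub panel, from what is known of the study, which chose its genes on these livers, so their direction is not independent evidence. Acot3 (NCBI gene 171281, chromosome 12, 84052144 to 84060400, GRCm38.p6), a peroxisomal acyl-CoA thioesterase, rose in all 3 polystyrene groups. Its level was 1.04 ± 0.77 CPM (counts scaled to library size) in water, 24.5 ± 18.5 at 80 nm, 25.1 ± 16.4 at 0.5 µm and 59.9 ± 35 at 5 µm (mean ± SD, n = 4). The log2 fold changes were 4.50 ± 0.76, 4.53 ± 0.76 and 5.78 ± 0.77 (± SE), with edgeR Benjamini-Hochberg adjusted p = 0.0197, 0.00328 and 0.000511. Abcc3 (76408, chromosome 11, 94343295 to 94393017), an efflux pump for bile acids and conjugates, rose 1.96-fold, 1.54-fold and 1.56-fold (edgeR Benjamini-Hochberg adjusted p = 0.018, 0.0332 and 0.0232). The constitutive androstane receptor gene Nr1i3 (12355, chromosome 1, 171213934 to 171218845) rose 2.65-fold at 0.5 µm and 2.91-fold at 5 µm (edgeR Benjamini-Hochberg adjusted p = 0.00135 and 0.000504). At 80 nm its fold of 1.79 was not called by edgeR (Benjamini-Hochberg adjusted p = 0.0538) and was called by DESeq2 (adjusted p = 0.00546). The exact permutation test (two-sided, n = 4 per group) gave p = 0.0286 for each of these comparisons except Abcc3 at 5 µm, where p = 0.0857. With limma-voom Acot3 was not called at 80 nm (adjusted p = 0.121) or 0.5 µm (adjusted p = 0.0709), and in a fit of only water and 5 µm Abcc3 was not called (adjusted p = 0.0783). With the clock score as a covariate, chosen after seeing the data, the errors widened, Acot3 at 80 nm stayed called (log2 6.17 ± 1.27 SE in place of 4.50 ± 0.76, edgeR adjusted p = 0.0474) and other calls ended. Abcc3 had log2 fold changes of 0.96 ± 0.28, 0.60 ± 0.57 and 0.63 ± 0.58 (± SE) in place of 0.97 ± 0.17, 0.62 ± 0.17 and 0.65 ± 0.17 (edgeR adjusted p = 0.105, 0.731 and 0.687). At 0.5 µm and 5 µm Acot3 had 8.83 ± 2.96 and 10.16 ± 2.97 (0.258 and 0.156), and Nr1i3 had 0.91 ± 0.71 and 1.04 ± 0.72 in place of 1.40 ± 0.22 and 1.54 ± 0.22 (0.658 and 0.568). Leaving out 80 nm replicate 3 lowered the Acot3 fold at 80 nm to 14.2, and leaving out single libraries ended the call of Acot3 in 2 of 8 cases at 80 nm and that of Abcc3 in 6 of 8 at 0.5 µm and 5 of 8 at 5 µm.

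**Figure D3:**
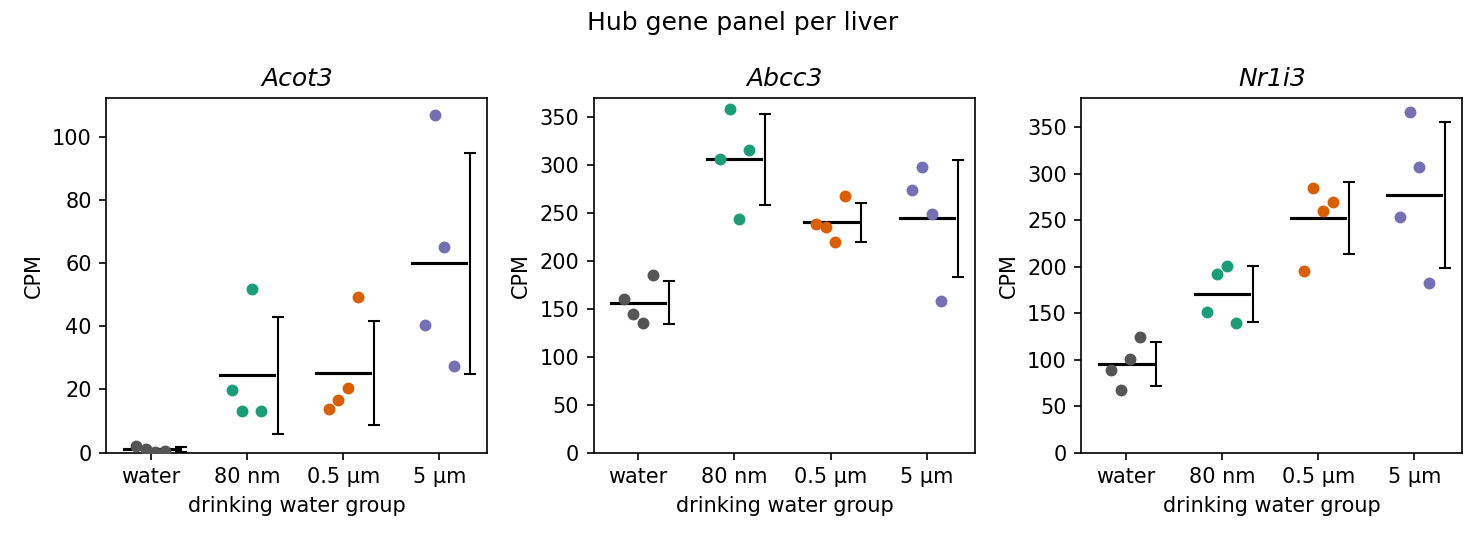
Levels of Acot3, Abcc3 and Nr1i3 in CPM on linear axes, with a point per liver, a line at the group mean and a bar of 1 SD each way. Acot3 is near 0 in the 4 water livers, with a mean of 1.04, and 59.9 at 5 µm.

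At 80 nm, some genes of fatty acid oxidation were higher and Mup genes lower than in water. Besides Acot3, its neighbours on chromosome 12, Acot1, Acot2 and Acot4, rose 4.41-fold, 3.57-fold and 2.78-fold (log2 2.14 ± 0.50, 1.84 ± 0.33 and 1.48 ± 0.29 SE, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 0.0421, 0.0197 and 0.0241). Without 80 nm replicate 3 Acot1 was no longer called (2.93-fold, edgeR adjusted p = 0.101). Acadm, which starts the oxidation of medium-chain fatty acids, rose from 245 ± 15.6 to 429 ± 74.5 CPM. Of 41 measured targets of the lipid sensor PPAR alpha and fatty acid oxidation genes, 9 rose, 0 fell and 32 were not called, and 31 rose when adjusted over the list alone. The list lay above other genes (camera, Benjamini-Hochberg adjusted p = 1.15e-17; adjusted p = 0.81 with an estimated correlation). Of 24 triglyceride and lipid droplet genes, Fitm2 (1.86-fold), which helps droplets form, and Hsd17b11 (1.46-fold), a droplet protein, rose, and 5 rose when adjusted over the list alone (camera adjusted p = 0.000306; adjusted p = 0.81 with an estimated correlation). Slc16a5, of the monocarboxylate transporter family, rose 4.45-fold, Rab30 3.07-fold, the cell cycle repressor E2f8 3.16-fold and Fzd6, a Wnt receptor, 3.15-fold.

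The falls at 80 nm included Mup17 (18.4-fold), Mup2 (4.92-fold) and Mup16 (21.7-fold), beside the lower summed Mup share of 11.6%. Apcs, the acute phase protein amyloid P, fell 2.48-fold (log2 -1.31 ± 0.17 SE, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 0.00384) and Orm1 1.75-fold. Those were the 2 called of 25 acute phase genes, 5 of which fell when adjusted over the list alone (camera adjusted p = 0.000768; adjusted p = 0.948 with an estimated correlation). Ptgds, a prostaglandin synthase, fell 6.26-fold, Nat8f5 4.13-fold, the calpain Capn8 3.92-fold and E-cadherin, Cdh1, 3.50-fold. Of 25 male-biased liver genes, Elovl3, a fatty acid elongase, and Cyp2u1 fell and 0 rose, 8 falling when adjusted over the list alone (camera adjusted p = 7.27e-05; adjusted p = 0.81 with an estimated correlation). That list holds several Mup genes, near-identical copies entered as separate members, so at each size its result is not independent of the Mup share. Elovl3 went from 499 ± 33.2 to 180 ± 76.2 CPM. Among 20 female-biased genes Acot3 and Acot4 rose and 0 fell, with 3 rising when adjusted over the list alone (camera adjusted p = 0.0517). Of 24 clock and output genes 7 rose and 0 fell, among them Dbp at 6.29-fold and Per3 at 2.76-fold, with 10 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.000757; adjusted p = 0.81 with an estimated correlation). The clock list mixes genes that move in opposite directions, and camera asks for a net shift. Its camera p, here and below, thus depends on how many of each kind were listed. None of 17 Kupffer cell and macrophage markers was called, 16 had negative values and the list lay below other genes (camera adjusted p = 0.0222; adjusted p = 0.948 with an estimated correlation), a call lost without water replicates 1 or 3 or 80 nm replicates 1 or 2 (adjusted p = 0.0539, 0.221, 0.0743 and 0.0787). None of 16 sinusoidal endothelial markers was called by edgeR, 16 had positive values, 1 rose when adjusted over the list alone, and the list lay above other genes (camera adjusted p = 0.000332; adjusted p = 0.948 with an estimated correlation).

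In total edgeR called 287 of 12298 genes at 80 nm, 156 higher and 131 lower, of which 68 changed at least 2-fold. Over all tested genes the livers of the 2 groups did not overlap in 11.6% (chance gives 2.86%). The count was 33 without water replicate 4, 61, 146, 60, 184, 59 and 118 without water replicates 2 and 3 and 80 nm replicates 1, 2, 3 and 4, 683 with DESeq2, 114 in a fit of only these 2 groups and 121 with the clock score as a covariate. Of those 121, 52 were also called in the main fit, in the same direction. Of 24 named called genes 2, Abcc3 and Apcs, stayed called without each library in turn and 7 with the clock covariate, and without water replicate 3 Dbp rose 15.8-fold, Mup16 fell 12.2-fold and Mup17 fell 11.0-fold. The 7 include Dbp, which is part of the clock score, so its call there decides nothing.

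Many clock genes changed at 0.5 µm. Dbp (NCBI gene 13170, chromosome 7, 45705100 to 45710203), a clock-driven transcription factor, rose from 5.84 ± 7.22 to 147 ± 9.80 CPM (mean ± SD, n = 4; log2 4.69 ± 0.64 SE, edgeR Benjamini-Hochberg adjusted p = 0.000768). The cell cycle kinase gene Wee1, a clock output, rose 11.2-fold and the clock repressor Per3 9.89-fold (edgeR Benjamini-Hochberg adjusted p = 3.46e-06 and 3.5e-06). Arntl (11865, chromosome 7, 113178471 to 113314126), which encodes the clock activator BMAL1, fell 17.8-fold (log2 -4.16 ± 0.29 SE, edgeR Benjamini-Hochberg adjusted p = 3.46e-06), and its partner Npas2 fell 27.1-fold. Npas2 had 13 summed counts in the 4 livers at 0.5 µm. Ciart and Usp2, both clock outputs, rose 11.7-fold and 8.99-fold. Of 24 clock and output genes 14 rose and 5 fell, and 14 rose and 6 fell when adjusted over the list alone (camera adjusted p = 7.86e-05; adjusted p = 0.81 with an estimated correlation), with the clock score higher by 6.53.

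Bile acid genes went both ways at 0.5 µm. Cyp7a1 (13122, chromosome 4, 6265612 to 6275632), the rate-limiting enzyme of bile acid synthesis, rose 8.43-fold (log2 3.08 ± 0.70 SE, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 0.0182). The bile acid receptor gene Nr1h4 rose 1.54-fold and the bile salt export pump Abcb11 fell 1.97-fold (edgeR Benjamini-Hochberg adjusted p = 0.00152 and 0.000306). Of 23 measured bile acid genes 3 rose, 4 fell and 16 were not called, with 5 rising and 7 falling when adjusted over the list alone (camera adjusted p = 0.778). Of 29 NRF2 targets and antioxidant genes, Gclc (2.15-fold), Gclm (1.31-fold) and Txn1 (1.44-fold) fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.00408; adjusted p = 0.948 with an estimated correlation), a list call lost without 0.5 µm replicate 3 (adjusted p = 0.0761). Gclc and Gclm make glutathione and Txn1 is thioredoxin. Of 24 triglyceride and droplet genes 5 rose, among them Dgat2 (1.65-fold), which makes triglyceride, and the lipase Lipe (2.01-fold), with 5 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.0222; adjusted p = 0.948 with an estimated correlation), a list call lost without water replicate 2 or 0.5 µm replicates 1 or 3 (adjusted p = 0.05, 0.0679 and 0.0848). Of 41 PPAR alpha and oxidation genes 7 rose, among them Cpt1a, the gate of mitochondrial fatty acid oxidation, at 1.63-fold, and 9 rose when adjusted over the list alone (camera adjusted p = 9.95e-07; adjusted p = 0.948 with an estimated correlation).

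Some genes with a sex bias in mouse liver also moved at 0.5 µm, beside the lower Mup share of 12.8%, and most were not called. Of 20 measured female-biased genes 5 rose, including Cux2 (12.4-fold) and Trim24 (2.02-fold), both transcription regulators, and 5 rose when adjusted over the list alone (camera adjusted p = 0.00761; adjusted p = 0.81 with an estimated correlation). Of 25 male-biased genes 3 fell, including Elovl3 (NCBI gene 12686, chromosome 19, 46131897 to 46135694) by 8.65-fold, with 4 falling when adjusted over the list alone (camera adjusted p = 0.00441; adjusted p = 0.948 with an estimated correlation). Slc16a5 rose 5.75-fold. Other large falls were Mup16 (19.2-fold), Mup17 (13.6-fold), the choline kinase Chka (6.87-fold), Ypel2 (5.38-fold) and the tubulin Tubb2a (5.31-fold). Among cell type markers, 1 of 16 sinusoidal endothelial genes, Bmp2, rose and 2 rose when adjusted over the list alone (camera adjusted p = 0.0148; adjusted p = 0.948 with an estimated correlation), a list call lost without water replicate 2 or 0.5 µm replicate 4 (adjusted p = 0.0843 and 0.123). Thrsp and Lipe rose among 7 adipocyte markers, both also when adjusted over the list alone (camera adjusted p = 0.0222; adjusted p = 0.81 with an estimated correlation), and both also act in hepatocytes.

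In total edgeR called 954 genes at 0.5 µm, 484 higher and 470 lower, 216 of them at least 2-fold, and 13.7% of all tested genes had no overlap of the 2 groups (chance gives 2.86%). The count was 575 without water replicate 4, 612 without 0.5 µm replicate 2, 591 in a fit of only these 2 groups and 20 with the clock score as a covariate. Of those 20, 5 were also called in the main fit, in the same direction. Of 28 named called genes 23 stayed called without each library in turn and 0 with the clock covariate. Without 0.5 µm replicate 4, which had 8.50 CPM of Cux2, that gene rose 4.84-fold, without water replicate 2 Npas2 fell 17.7-fold, and without water replicate 3 Dbp, Ciart, Usp2 and Cyp7a1 rose 65.4-fold, 108-fold, 23.0-fold and 14.6-fold and Mup16 and Mup17 fell 10.8-fold and 8.11-fold.

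At 5 µm the same clock genes stood out. Dbp rose to 188 ± 14.2 CPM (33.1-fold; log2 5.05 ± 0.64 SE, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 0.000389), Wee1 rose 15.4-fold, the clock repressor Bhlhe41 14.5-fold and Per3 11.1-fold. Arntl fell 12.9-fold and Npas2 19.2-fold, the latter to 19 summed counts in the 4 livers. Of 24 clock and output genes 14 rose and 6 fell, and as many when adjusted over the list alone (camera adjusted p = 0.000135; adjusted p = 0.81 with an estimated correlation), with the clock score higher by 6.53. The 14 higher genes were the same at 0.5 µm and 5 µm, as were 5 of the lower.

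Some lipid synthesis genes rose at 5 µm. Thrsp, a regulator of lipogenesis, rose 7.90-fold (log2 2.98 ± 0.58 SE, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 0.00708) and the lipogenic transcription factor Srebf1 2.19-fold (adjusted p = 0.0302 with edgeR). They were among 4 of 18 fatty acid synthesis genes that rose, also 4 when adjusted over the list alone (camera adjusted p = 0.00347; adjusted p = 0.948 with an estimated correlation). Of 24 cholesterol genes 4 rose and 0 fell, also 4 when adjusted over the list alone (camera adjusted p = 0.00281; adjusted p = 0.948 with an estimated correlation), a list call lost without water replicate 3 (adjusted p = 0.0682). Of 24 triglyceride and droplet genes 2 rose and 0 fell, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.057). Of 7 adipocyte markers, Thrsp among them, 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0512). Cyp7a1 rose 8.06-fold. Of 41 PPAR alpha and oxidation genes 7 rose, including Acot4 (4.21-fold), Acot2 (3.53-fold) and Hadh (1.27-fold), with 8 rising when adjusted over the list alone (camera adjusted p = 6.68e-06; adjusted p = 0.948 with an estimated correlation).

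Some protein folding genes fell at 5 µm. The endoplasmic reticulum chaperones Hspa5, Hyou1 and Dnajb9 fell 2.30-fold, 2.76-fold and 1.95-fold and Edem1, which sends misfolded proteins to degradation, 1.54-fold (edgeR Benjamini-Hochberg adjusted p = 0.0137, 0.0106, 0.0024 and 0.000127). Of 22 unfolded protein response genes 7 fell, 0 rose and 15 were not called, and 8 fell when adjusted over the list alone (camera adjusted p = 7.08e-05; adjusted p = 0.81 with an estimated correlation). The cell cycle inhibitor Cdkn1a fell 14.2-fold, Ddit4, an inhibitor of mTOR, 12.2-fold and the heat shock gene Hspa1b 11.7-fold. Ddit4 stood at 47.2 CPM in water replicate 3 and at 6.47 or less in the other water livers, and its call ended without that liver (edgeR adjusted p = 0.0879). Of 20 immediate early genes, which respond to tissue handling among other stimuli, 1 fell, 0 rose, 15 had negative values and 0 were called when adjusted over the list alone (camera adjusted p = 0.0481; adjusted p = 0.948 with an estimated correlation), a list call lost without water replicates 2 or 3 or 5 µm replicates 2, 3 or 4 (adjusted p = 0.133, 0.208, 0.102, 0.114 and 0.2). Of 25 male-biased genes 5 fell, Elovl3 by 9.79-fold, and 8 fell when adjusted over the list alone (camera adjusted p = 2.76e-05; adjusted p = 0.81 with an estimated correlation). Of 20 female-biased genes 4 rose, and 5 when adjusted over the list alone (camera adjusted p = 0.00408; adjusted p = 0.81 with an estimated correlation). Mup17 fell 17.3-fold and Mup16 15.1-fold, beside the lower Mup share of 11.8%. The male-biased fallers included Mup1, Mup7 and Mup21 and the female-biased risers Acot3 and Acot4. The male-biased list result thus partly repeats the lower Mup share.

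Fibrosis genes did not rise as a group at 5 µm. Of 37 collagen and matrix genes 1 rose, 0 fell, 36 were not called and 30 had negative values, with 0 called when adjusted over the list alone. The list lay below other genes (camera adjusted p = 0.0234; adjusted p = 0.948 with an estimated correlation), a call lost without water replicate 2 or 5 µm replicates 3 or 4 (adjusted p = 0.67, 0.0935 and 0.118). Of 15 stellate cell markers Ecm1, a matrix protein, fell 1.44-fold and 0 rose, with 2 falling when adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.948 with an estimated correlation), a list call lost without water replicate 2 or 5 µm replicate 3 (adjusted p = 0.143 and 0.0505). Without water replicate 2, 9 lists were called at 5 µm in place of 14. The MHC class II gene H2-Eb1 rose 58.5-fold, from 15 summed counts in the 4 water livers. It reached 51.3 CPM in 5 µm replicate 1 and between 2.69 and 3.58 in the other 5 µm livers. None of 27 interferon response genes was called, 22 had positive values and the list lay above other genes (camera adjusted p = 0.0356; adjusted p = 0.948 with an estimated correlation), a call lost without water replicates 2 or 4 (adjusted p = 0.0638 and 0.242) and turned in direction without 5 µm replicate 1 (adjusted p = 0.978).

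In total edgeR called 1191 genes at 5 µm, 616 higher and 575 lower, 304 of them at least 2-fold, and 15.8% of all tested genes had no overlap of the 2 groups (chance gives 2.86%). The count was 750 without water replicate 4 and 60 with the clock score as a covariate. Of those 60, 21 were also called in the main fit, in the same direction. Of 27 named called genes 22 stayed called without each library in turn and 1, Ddit4, with the clock covariate. Without 5 µm replicate 1 H2-Eb1 rose 12.2-fold, without water replicate 2 Npas2 fell 12.6-fold, and without water replicate 3 Ddit4 was no longer called (2.95-fold lower, edgeR adjusted p = 0.0879), Dbp, Cyp7a1 and Thrsp rose 83.7-fold, 13.9-fold and 12.8-fold and Cdkn1a, Mup16 and Mup17 fell 9.32-fold, 8.43-fold and 10.3-fold.

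The difference between particle sizes at the same concentration was tested directly. Arntl was 11.6-fold higher at 80 nm than at 0.5 µm (log2 3.53 ± 0.29 SE, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 3.46e-05) and Npas2 10.5-fold higher. Ciart, Cux2 and Usp2 were 12.9-fold, 9.56-fold and 7.95-fold lower at 80 nm. Cux2 had 21 summed counts at 80 nm and Npas2 13 at 0.5 µm. Of 24 clock genes 4 were higher and 9 lower, and 7 higher and 13 lower when adjusted over the list alone (camera adjusted p = 0.0169, or 0.0592 without 80 nm replicate 2 and 0.0564 without 0.5 µm replicate 4; adjusted p = 0.925 with an estimated correlation), with the clock score lower by 4.13 at 80 nm (difference -4.13). Gclc and Gclm, both glutathione synthesis genes, were 2.17-fold and 1.40-fold higher, the 2 called of 29 NRF2 targets, also when adjusted over the list alone (camera adjusted p = 0.0065, or 0.0545 without 80 nm replicate 4 and 0.112 without 0.5 µm replicate 3; adjusted p = 0.948 with an estimated correlation). Of 24 cholesterol genes 1 was lower and 0 were higher, and 6 were lower when adjusted over the list alone (camera adjusted p = 0.000768; adjusted p = 0.948 with an estimated correlation). Of 7 named genes 3 stayed called without each library in turn. With the clock covariate 1 did, Arntl, which is part of the clock score, so that call decides nothing. In total 549 genes differed, 302 higher and 247 lower at 80 nm. The count was 300, 339, 313 and 312 without 80 nm replicates 3 and 4 and 0.5 µm replicates 1 and 2, 901 with DESeq2 and 6 with the clock score as a covariate, and Cux2 was no longer called without 0.5 µm replicate 4 (3.73-fold lower, edgeR adjusted p = 0.0732). Of those 6, 3 were also called in the main fit, in the same direction.

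Cholesterol synthesis genes separated 80 nm from 5 µm. Fdft1 and Dhcr7, enzymes of that pathway, were each 2.50-fold lower at 80 nm (log2 -1.32 ± 0.27 and -1.32 ± 0.33 SE, n = 4 per group; edgeR Benjamini-Hochberg adjusted p = 0.0102 and 0.0292). Of 24 cholesterol genes 10 were lower and 0 higher, and 12 lower when adjusted over the list alone (camera adjusted p = 8.94e-07; adjusted p = 0.948 with an estimated correlation). Thrsp was 10.4-fold lower, with Usp2 8.24-fold and Ciart 10.7-fold lower. Arntl was 8.39-fold, Cdkn1a 8.80-fold and the mesothelial gene Upk3b 11.1-fold higher, beside a clock score lower by 4.14 at 80 nm (difference -4.14). Of 27 interferon response genes the nucleic acid sensor Zbp1 (3.96-fold) and the immunoproteasome genes Psmb9 (3.40-fold) and Psmb8 (2.30-fold) were lower, 11 when adjusted over the list alone (camera adjusted p = 7.27e-05; adjusted p = 0.948 with an estimated correlation). Without 5 µm replicate 1 Zbp1 was no longer called (2.56-fold lower, edgeR adjusted p = 0.0991) and Psmb9 was 2.14-fold lower. Of 11 named genes 4 stayed called without each library in turn. With the clock covariate 1 did, Arntl, which is part of the clock score, so that call decides nothing. In total 951 genes differed, 470 higher and 481 lower at 80 nm. The count was 576, 486, 592, 543 and 538 without 80 nm replicates 1, 3 and 4 and 5 µm replicates 1 and 3 and 79 with the clock score as a covariate, and without 5 µm replicate 2 Upk3b was 19.7-fold higher. Of those 79, 28 were also called in the main fit, in the same direction. Upk3b had 10 summed counts in the 4 livers at 5 µm.

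Between 0.5 µm and 5 µm edgeR called 0 genes. At an unadjusted p under 0.05 there were 1065, where chance gives 615, the smallest adjusted p was 0.161, DESeq2 called 57 genes and limma-voom 0, a fit of only these 2 groups called 1, and 3 were called without 0.5 µm replicate 2. The median SE of the log2 fold change was 0.15, so that for a typical gene the unadjusted 95% interval reached 0.29 on either side of the estimate. Larger differences can be missed too, since between 31.3% and 38.8% of genes changed 1.5-fold were recovered in simulated comparisons with water. Of the 34 gene lists 14 differed by camera and 0 with an estimated correlation (smallest adjusted p = 0.81 with an estimated correlation). None of 22 unfolded protein response genes was called over all genes, and 6 were higher at 0.5 µm when adjusted over the list alone (camera adjusted p = 0.000156; adjusted p = 0.81 with an estimated correlation). None of 29 NRF2 targets was called, and 2 were lower at 0.5 µm when adjusted over the list alone (camera adjusted p = 1.77e-07; adjusted p = 0.81 with an estimated correlation).

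**Figure D4:**
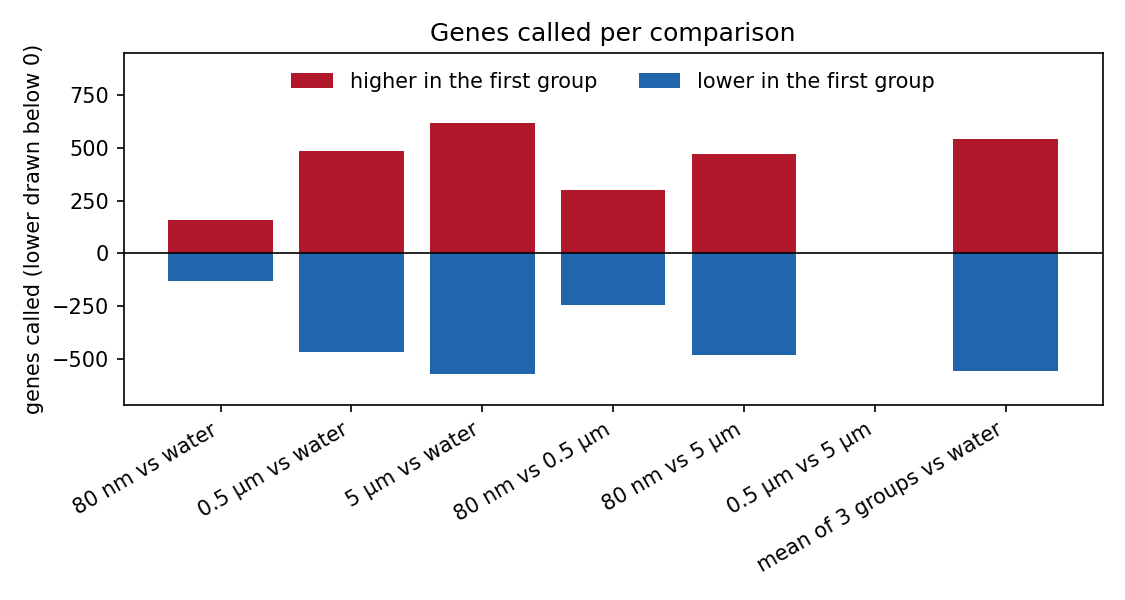
Number of genes called by edgeR at an adjusted p below 0.05 in each comparison, with genes higher in the group named before "vs" above 0 and genes lower drawn below 0. The counts run from 0 between 0.5 µm and 5 µm to 1191 for 5 µm against water.

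Taking the 12 polystyrene livers against the 4 water livers, the mean of the 3 groups was higher for Acot3 by 30.6-fold, Nr1i3 by 2.40-fold and Abcc3 by 1.67-fold (log2 4.94 ± 0.72, 1.26 ± 0.19 and 0.74 ± 0.14 SE; edgeR Benjamini-Hochberg adjusted p = 0.00112, 0.000967 and 0.00466). Dbp rose 17.5-fold, Wee1 7.66-fold, the ion channel gene Hcn3 3.91-fold, Ranbp3l 3.84-fold and the transcription regulator Tox 3.25-fold, Cyp7a1 rose 4.76-fold and Elovl3 fell 6.16-fold. Ranbp3l and Tox had 22 and 24 summed counts in the 4 water livers. Genes of fibrosis were not called: the log2 fold changes were -1.10 ± 0.59 for collagen Col1a1, -1.03 ± 0.47 for Col3a1, -0.34 ± 0.58 for the myofibroblast actin Acta2 and 0.17 ± 0.17 for Tgfb1 (edgeR Benjamini-Hochberg adjusted p = 0.278, 0.2, 0.774 and 0.58). Of 37 collagen and matrix genes none was called over all genes or adjusted over the list alone, and 32 had negative values (camera adjusted p = 0.0706). Water replicate 2 held 78.4 CPM of Col3a1 against 15.9 or less in the other water livers, and without it the log2 fold changes of Col1a1, Col3a1 and the fatty acid synthase gene Fasn were 0.46, 0.01 and 0.52. Without water replicate 1 the log2 fold change of Acta2 was 0.51. Of 24 triglyceride and droplet genes 4 rose and 1 fell, and 9 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00347; adjusted p = 0.869 with an estimated correlation). The 4 single lipid genes fixed beforehand were not called, with log2 fold changes of 1.28 ± 0.66 for the fatty acid transporter Cd36, 0.65 ± 0.50 for the desaturase Scd1, 0.35 ± 0.31 for the droplet coat Plin2 and -0.10 ± 0.27 for Fasn (edgeR Benjamini-Hochberg adjusted p = 0.256, 0.464, 0.547 and 0.862). Log2 levels of Plin2 differed from water by 0.84, -0.02 and 0.04 from the smallest to the largest size. At 80 nm edgeR called none of the 4, and unadjusted exact permutation p was 0.0286 for Plin2, 0.0571 for Cd36, 0.114 for Scd1 and 0.886 for Fasn. Cyp2b10, a target of Nr1i3, and Cyp1a1, a target of the aryl hydrocarbon receptor, had values of -0.45 ± 0.73 and 0.40 ± 0.39 (edgeR Benjamini-Hochberg adjusted p = 0.764 and 0.579), and without water replicate 4 that of Cyp2b10 was 1.22. Of 29 targets of Nr1i3 and the related receptor PXR, among them Abcc3 and Nr1i3, 1, 3 and 3 rose and 0 fell from the smallest to the largest size (camera adjusted p = 0.414, 0.657 and 0.0436; adjusted p = 0.948 with an estimated correlation at 5 µm), and 3 rose at each size when adjusted over the list alone. The call at 5 µm was lost without water replicates 1 or 2 or 5 µm replicates 1, 2 or 3 (adjusted p = 0.0776, 0.159, 0.0509, 0.189 and 0.11). In total 1104 genes were called, 543 higher and 561 lower, and of 10 named called genes 7 stayed called without each library in turn and 0 with the clock covariate. The count was 694, 725 and 573 without water replicates 1, 2 and 4 and 40 with the clock score as a covariate, and without water replicate 3 Dbp rose 44.2-fold and Cyp7a1 8.21-fold. Of those 40, 15 were also called in the main fit, in the same direction.

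The responses to the 3 sizes were compared over 12298 genes. Acot3 was among 61 genes higher in all 3 comparisons with water, and Elovl3 among 35 lower in all 3. Between 80 nm and 0.5 µm, 80 genes were higher in both and 45 lower in both, where independent lists would share 6.14 and 5.01. Between 80 nm and 5 µm these were 69 and 46, where independent lists would share 7.81 and 6.12, and between 0.5 µm and 5 µm 318 and 324, where independent lists would share 24.2 and 22. The comparisons share the same 4 water livers, which the figures for independent lists leave out of account. In 20 simulations of unchanged groups against shared controls the mean was 0, 0.1 and 0 shared calls. Those groups held no changes, so few genes can be called in them. The simulations thus do not show how many of the real shared calls come from the common livers. The log2 fold changes correlated across genes, which are not independent replicates, at r = 0.604 for 80 nm and 0.5 µm, 0.563 for 80 nm and 5 µm and 0.764 for 0.5 µm and 5 µm, against simulated values of 0.508, 0.508 and 0.513. The covariances were 0.108, 0.108 and 0.165 against simulated values of 0.0404, 0.0402 and 0.0407, which leaves 0.0674, 0.0679 and 0.125. With the water livers split so that each comparison used its own pair, the correlations were 0.204 to 0.434, 0.225 to 0.384 and 0.40 to 0.555. The simulated values above hold for shared livers and are no reference for these. Pairs of livers also give noisier fold changes, which lowers a correlation. The covariances in the splits had medians of 0.0656, 0.0652 and 0.123, beside the 0.0674, 0.0679 and 0.125 left above.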

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

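Chosen after the results were seen were the correlation without the library farthest in clock score, the hour of collection, the summed Mup and Acot tests, the slope of the Mup share on the clock score and the comparison of slopes with the slope that would be needed, and the fit without Mup genes was an added alternative. In 6 of 76 groups of 4 livers 1 liver lay far from the other 3, where chance gives about 1 in 20, or 3.8. Cyp2b10 stood at a log2 level of 3.15 in water replicate 4 (others -0.11 to 0.17) and at -1.46 in 0.5 µm replicate 3 (others 1.38 to 1.59). Col1a1 stood at 3.03 in 5 µm replicate 1 (1.41 to 1.66), Col3a1 at 6.30 in water replicate 2 (3.83 to 4), Tgfb1 at 3.02 in water replicate 1 (2.73 to 2.74) and Plin2 at 10.1 in 80 nm replicate 3 (9.19 to 9.32). A direct test of the difference between sizes called 549 genes for 80 nm against 0.5 µm and 951 for 80 nm against 5 µm.

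Chance was tested by fitting other splits of the same libraries. For 80 nm against water the real split called 287 genes and the highest other of 35 splits 7. For 0.5 µm and 5 µm against water these were 954 and 1, and 1191 and 3. They were 549 and 1 for 80 nm against 0.5 µm, and 951 and 2 for 80 nm against 5 µm. For the mean of the 3 groups the real split called 1104 and the highest other of 100 splits drawn 32. In each, 1 split, the real one, called as many, so a random grouping is unlikely. It is not excluded, since 35 splits can give no smaller share than 1 in 35. The other splits mix the groups, so their counts are not those of groups without a difference. Anything else that differed with the group would give the same result. For 0.5 µm against 5 µm the real split called 0 genes, so that all 35 splits called as many by necessity (0 in the highest other), and the splits decide nothing.

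The calls against water at 0.5 µm and 5 µm came with a clock score higher by 6.53, so a difference in clock phase of the liver may explain part of them. At 80 nm the score was higher than in water by 2.39, and it differed from 0.5 µm and 5 µm by -4.13 and -4.14. The same may hold for the calls in those comparisons. Across 12292 genes the slope on the clock score within groups correlated with the 5 µm fold change at 0.036 (21 of 100 as large, with the observed value counted among the 100 beside within-group permutations, whose 95th percentile was 0.0684), which met the bound written before this test against clock phase. The score itself was defined after the data were seen, so that bound does not predate the clock values. Water replicate 3 held 54.7% of the within-group spread in clock score, and without it the correlation was 0.158 (4 of 100 as large, counted in the same way, highest permuted 0.201), so the bound was not met there, and the rule that it must be met without that library too was added after the value was seen. At 5 µm 8 of 10 genes that peak near dusk were higher and 5 of 5 that peak near dawn lower, so 13 went the way set for a later phase and 0 the other way. A different hour of collection would also give that pattern. These genes belong to the clock list counted above and include all genes of the score, so their count adds nothing to it. Opposite sets that move apart do not tell a later phase from an earlier one. The labels give no hour, so clock phase, hour of collection and an effect of the particles on the clock cannot be told apart.

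The Mup share was higher in water than in each polystyrene group. Counts split between near-identical copies would leave the family sum unchanged, and the sum differed at 5 µm (exact permutation p = 0.0286, two-sided, n = 4 per group). That sum and p are those given above for the share, so the test adds nothing to them. With the Mup genes left out 1163 genes were called at 5 µm, but TMM already offsets such a shift and no library's scaling moved by more than 0.0116 (log2), so whether Mup genes take counts from other genes was not decided. Clock phase needs a Mup share that falls with the clock score within groups, and the slope was 2.75 percent per unit (one-sided permutation p = 0.105 for a slope above 0), or 0.287 without water replicate 3. Phase as the whole cause needs a slope of -1.89, which lay outside the 95% interval with all libraries (0.621 to 4.88) but not without water replicate 3, so clock phase stays open. A change in the sex-biased program of the liver may be involved, which was not tested apart from the groups.

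Acot3 and Nr1i3 were higher in the polystyrene groups. Reads moved between Acot paralogs would leave the summed level of Acot1 to Acot4 unchanged (Acot5 and Acot6, also in the set, did not pass the filter), and the sum rose from 34.9 ± 7.07 to 153 ± 74.3 CPM at 5 µm (exact permutation p = 0.0286, two-sided, n = 4 per group). The sum shows that the family rose but not which member did. Reads of a rising paralog assigned to Acot3 are thus not excluded. Within groups the slope on the clock score was -0.477 for Acot3 (-0.562 to -0.378 with single libraries left out) and 0.0872 for Nr1i3. The Acot3 slope met the bound written before this test against clock phase, with all libraries and without each, on a score defined after the data were seen. A linear effect of phase as the whole cause at 5 µm needs a slope of 0.881, which lay above the 95% interval (-1.05 to 0.0978), also without each of the 16 libraries. Water replicate 3 held 54.7% of the within-group spread in clock score, and Acot3 was near the floor in water (1.04 ± 0.77 CPM). A slope resting on such livers cannot decide over a score difference of 6.53, so phase stays open for Acot3 as well. For Nr1i3 the needed slope of 0.234 lay inside the interval (-0.149 to 0.323), so phase stays open there, and an effect of the particles on either gene remains a hypothesis.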

How the results depend on the processing

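The clock score as a covariate and leaving out the Mup genes were chosen after seeing the data. Dbp, Tef, Per3, Arntl, Npas2 and Clock make up the clock score, so with it as a covariate their own calls and reversals decide nothing. The clock score is nearly fixed by group, so that fit extrapolates and has wider errors, and a call lost in it may come from either. It called 121, 20, 60, 6, 79 and 40 genes (against water from the smallest to the largest size, 80 nm against 0.5 µm and against 5 µm, mean of 3), and 0 between 0.5 µm and 5 µm. Of those, 52, 5, 21, 3, 28 and 15 were main calls in the same direction. In it these log2 fold changes reversed: at 0.5 µm Dbp -0.55, Ciart -5.71, Usp2 -2.33, Npas2 3, Cyp7a1 -0.073, Gclc 0.34 and Cpt1a -0.036; at 5 µm Dbp -0.18, Npas2 3.48, Cyp7a1 -0.10 and Thrsp -1.08; for 80 nm against 0.5 µm Npas2 -1.19, Usp2 0.87 and Ciart 3.20, and against 5 µm Usp2 0.85 and Ciart 3.53; for the mean of 3 Cyp7a1 -0.10, Fasn 1.71, Col1a1 3.72, Col3a1 1.94, Acta2 1.14, Cyp1a1 -1.18 and Tox -0.28. Nr1i3 was 0.91 at 0.5 µm and 1.04 at 5 µm, Abcc3 0.96, 0.60 and 0.63 from the smallest to the largest size, and Acot3 8.83 and 10.16 at 0.5 µm and 5 µm, none of these called. The cause was not tested.

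DESeq2 called 683 genes at 80 nm, 901 for 80 nm against 0.5 µm and 57 between 0.5 µm and 5 µm, and called Nr1i3 at 80 nm (log2 0.84), as did the stricter filter (0.84). With limma-voom Acot3 was not called at 80 nm (4.49) or 0.5 µm (4.59) and Fasn in the mean of 3 was 0.10 in place of a negative value. A fit of only the groups compared called 114 genes at 80 nm, 591 at 0.5 µm and 1 between 0.5 µm and 5 µm, did not call Abcc3 at 5 µm (0.65), and gives no separate value for the mean contrast. With at least 2-fold change as well the counts were 68, 216, 304, 105, 181 and 179 in the order above. With unadjusted p and 2-fold they were 389, 508, 247, 378, 297 and, between 0.5 µm and 5 µm, 164 (80 nm stayed near the reported count at 270). Camera with an estimated correlation called 0 lists in all 7 comparisons. With Mup genes left out the counts were 269, 957 and 1163 against water. The cause was not tested.

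With 1 library left out at a time the counts ran from 33 to 274 (80 nm), 575 to 973 (0.5 µm), 750 to 1099 (5 µm), 300 to 456 and 486 to 860 (80 nm against 0.5 µm and 5 µm), 0 to 3 (0.5 µm against 5 µm) and 573 to 1097 (mean). Lists called ran from 10 to 14, 7 to 12, 9 to 16, 5 to 8, 8 to 11, 8 to 16 and 9 to 13, and 7, 5, 7, 2, 4, 4 and 8 lists stayed called without each library. Log2 fold changes ran from 0.71 to 1.00, 1.27 to 1.56 and 1.38 to 1.70 for Nr1i3, 0.89 to 1.07, 0.56 to 0.72 and 0.54 to 0.81 for Abcc3 and 3.83 to 5.06, 3.97 to 5.09 and 5.35 to 6.34 for Acot3. In the mean of 3 Fasn ran from -0.31 to 0.52, Col1a1 from -1.40 to 0.46 and Col3a1 from -1.27 to 0.010, reversed without water replicate 2, Acta2 from -0.59 to 0.51, reversed without water replicate 1, and Cyp2b10 from -0.76 to 1.22, reversed without water replicate 4. With the water livers split 2 and 2 the correlations of responses had medians of 0.297, 0.276 and 0.476 and ranges of 0.204 to 0.434, 0.225 to 0.384 and 0.40 to 0.555.

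With the replicate number as a block the counts were 253, 885, 1134, 509, 855, 0 and 1042. The labels give equal numbers no meaning. The 24 pairs of equal number correlated between -0.125 and 0.19 (median 0.00729, against 0.00845 for other pairs), 4 of them above 0.1, and 7 of 16 libraries matched their own number best. Of 109 further values of genes named in the text 99 were called, 3 of them in every setting. In at least 1 setting 91 lost the call with the direction kept, and 18 changed direction, and these counts overlap. That set was narrowed to the named genes after its output was seen. Over all 401 values the naming rule takes, 317 were called, 5 of them in every setting. In at least 1 setting 300 lost the call with the direction kept, and 38 changed direction, and these counts overlap. Outside the clock covariate 0 called values reversed.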

Other observations

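No test in this part was chosen after its result was seen. Genes for several other responses gave no calls against water. Of 9 aryl hydrocarbon receptor targets, 19 inflammatory genes and 9 red blood cell genes edgeR called 0 at each size, with camera Benjamini-Hochberg adjusted p = 0.739, 0.974 and 0.667, 0.436, 0.928 and 0.53, and 0.821, 0.814 and 0.736 from the smallest to the largest particle. Of 8 cholangiocyte markers Sox9, a duct and progenitor factor, fell at 0.5 µm and 5 µm. Sox9 was named after its values were seen.

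Several lists shifted between 0.5 µm and 5 µm although edgeR called 0 genes there, 1065 at an unadjusted p under 0.05, with 57 by DESeq2 and 0 by limma-voom. Of 27 interferon genes 26 lay lower at 0.5 µm (camera Benjamini-Hochberg adjusted p = 0.00219; adjusted p = 0.948 with an estimated correlation), as did 23 of 24 cholesterol genes (camera adjusted p = 0.0038; adjusted p = 0.948 with an estimated correlation). The interferon call was lost without 0.5 µm replicate 1 (adjusted p = 0.0525) and turned without 5 µm replicate 1 (0.846), and the cholesterol call was lost without 0.5 µm replicates 2 or 4 or 5 µm replicates 3 or 4 (0.056, 0.169, 0.178 and 0.0778). Of 15 stellate cell markers 13 lay higher (camera adjusted p = 0.000149; adjusted p = 0.925 with an estimated correlation). At 80 nm against water 32 of 35 nuclear respiratory chain genes and 36 of 43 ribosomal protein genes lay lower, none called by edgeR, with median log2 fold changes of -0.09 and -0.07 (camera adjusted p = 0.00393 and 0.0231; adjusted p = 0.948 with an estimated correlation for both). The respiratory chain call was lost without water replicate 3 (adjusted p = 0.0837) and the ribosomal call without water replicates 1 or 3 or 80 nm replicates 2, 3 or 4 (0.0563, 0.107, 0.102, 0.218 and 0.051).

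TMM factors were 0.881 ± 0.0992 in water and 1.04, 1.04 and 1.06 in the polystyrene groups. Albumin took 5.59%, 7.14%, 5.75% and 6.39% of counts in water and from the smallest to the largest size. The leading principal components held 19.2%, 11.4%, 9.76% and 9.32% of the variance.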
